A study of Mus musculus with 11 samples.

How the data were processed

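The series holds 11 RNA sequencing libraries of ribosome-bound RNA, 1 per mouse, from 4 knockout and 7 control cerebella taken at postnatal day 56. The labels tie each library to a separate animal tag, and nothing else supports treating the libraries as replicates. Each deposited file holds whole-number read counts per gene for 1 library, which per the submitters' processing notes came from STAR alignment to GRCm38 and HTSeq counting. Tool versions, counting options, strand setting and any removal of duplicate reads are not given in the sources used here. The counts carry no normalization, and reads without molecular identifiers are not independent molecules.

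Each file lists 55421 genes and 5 summary lines that name no gene. These lines stayed out of library totals and tests. Reads outside any gene made up 7.16% ± 0.557 of all counted alignments in controls and 9.07% ± 2.09 in knockouts, alignments to several places 8.41% ± 0.531 and 9.77% ± 0.807, and ambiguous ones 4.10% ± 0.191 and 3.95% ± 0.0870 (SD, n = 7 and 4). The most similar pair of libraries differed by a chi-square per degree of freedom of 2.45, more than sampling noise, so no library was counted as a copy of another. The depth per library ranged from 2.58 to 5.14 M reads in genes, and the 100 most counted genes took 5.20% to 6.51% of them.

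Genes were tested with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr on the group, which left 13375, library totals were scaled with TMM factors, and a quasi-likelihood model with batch and genotype was fitted with 7 residual degrees of freedom. P-values were two-sided and adjusted by Benjamini-Hochberg over all tested genes with a threshold of 0.05. CPM values are TMM-scaled, log2 CPM used a prior count of 2, and within-batch log2 ratios of mean CPM a pseudocount of 0.5 CPM. Group means in CPM are not adjusted for batch, so they can differ from the fitted fold changes. No batch was tested alone, since batch 1 holds 2 knockouts against 1 control, batch 2 1 against 1, and batch 3 1 against 5. A standard error of a fold change is the fold change divided by the root of its F statistic. With simulated counts for these 13375 genes and 200 changed genes, the model called 62% of genes changed 2-fold and 75% of those changed 4-fold, and 9 unchanged genes. The counts were drawn independently for each gene around a fit with batch alone. They hold no shift in cell mixture tied to genotype and no levelling off with depth. The 9 calls therefore say nothing on false calls from such differences.

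Before the data were examined, 27 gene lists were fixed: cell types of the cerebellum, Tie2 and VEGF signalling, guidance, dendrite growth, synapses, channels, matrix, energy metabolism, ribosomes, stress, immediate early genes, FoxO targets and cholesterol synthesis. The tested lists, 26 in all, had at least 3 measured members. They were compared with the other genes by camera in limma 3.58.1 with a preset correlation of 0.01 and with an estimated correlation, and tested against no change by fry, which asks a different question, adjusted over the lists. By camera 6 lists passed with the preset and 0 with the estimated correlation; fry called 6 lists in 1 direction and 23 in either.

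Named genes followed a fixed rule. Tek was always named, with the 12 largest positive and 12 largest negative log2 fold changes among called genes of at least 1 mean CPM that kept their sign in all 3 batches and had no predicted-gene symbol, and up to 4 members per list with the smallest p that passed over the list alone. This gave 105 genes, of which 3 are not reported here. Positions came from the RefSeq table of the same build, which matched 12872 tested genes (96.2%) by symbol. For genes with 0 reads in a group the fold is a bound against 3 counts over the group; for those with 1 to 3 reads the ratio of pooled counts is given with an exact binomial 95% interval.

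Alternatives fixed in advance were no batch term, DESeq2 size factors, library totals alone, 2 other filters on low counts, each library left out in turn, animals tagged M only, the tag letter or a purity score as covariate, the Wald test of DESeq2 1.42.0, limma-voom with sample weights, batch as a random block, other thresholds and other windows around Tek. Batch 2 left out, the library total as covariate and thinning to the smallest library were added after the data were seen. Of 330 splits of the libraries into 4 and 7, 100 were drawn and refitted, the real one included, and after that the 28 splits that exchange 1 knockout for 1 control.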

Results

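The series measured the RNA bound to ribosomes of Purkinje cells, the only output neurons of the cerebellar cortex, in mouse cerebellum on postnatal day 56. In the RiboTag method used here, Cre recombinase under the Pcp2 promoter switches on a tagged copy of the ribosomal protein Rpl22 in Purkinje cells, and an antibody against the tag then pulls down their ribosomes with the attached RNA from whole tissue. In 4 knockout animals, per the labels, the same Cre also acts on floxed alleles of Tie2, a receptor tyrosine kinase for angiopoietins that is encoded by Tek, while 7 control animals carried only the Cre and the tagged ribosome. The question was how the ribosome-bound RNA of Purkinje cells differs when they lack Tie2. The labels give 3 batches, with 2 knockouts and 1 control in batch 1, 1 of each in batch 2, and 1 knockout and 5 controls in batch 3. Libraries are named by group and animal tag.

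Reads counted in genes numbered 2.58 to 4.2 M in the knockouts (3.38 M ± 0.66 SD, n = 4) and 4.09 to 5.14 M in the controls (4.57 M ± 0.394 SD, n = 7). Within batches the log2 library total was 0.47 lower in the knockouts (two-sided exact permutation p = 0.0278 over 36 arrangements, the smallest this design allows). A count of 3, used as the detection floor, corresponded to 0.222 CPM (counts scaled to a common library total) over the pooled knockouts and 0.0945 CPM over the pooled controls; floors and intervals cover counting error only. At least 1 read was counted in 17843 ± 515 genes in the knockouts and 20443 ± 1397 in the controls (SD).

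Tek had 0 to 40 reads per library and could not check the labels. It had 21 reads in the 4 knockout libraries together and 93 in the 7 controls, with 0 reads in knockouts F371 and M390 and in control M386, and 40 in control M480. Knockout M456, with 14 reads (5.62 CPM), was above 6 of the 7 controls and below only M480 (7.94 CPM). The mean was 1.93 CPM ± 2.65 in the knockouts and 2.81 CPM ± 2.75 in the controls (SD, n = 4 and 7), and the fitted log2 fold change of 0.87 ± 0.95 (SE) did not pass the test (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.52). Its sign turned to -0.64 when the batch term was left out. The gene, ENSMUSG00000006386, lies on chromosome 4 from 94739086 to 94874976 in GRCm38. A gene-level count also holds reads outside the deleted part and reads from vessel RNA carried along. Cldn5, a tight junction protein of brain endothelium, varied with Tek between libraries, from 13 reads in control M386 to 249 in control M480. Xist, which is transcribed from the inactive X chromosome of females, had 11 reads in knockout F371 and 41 in control F473, and 0 or 1 in the animals tagged M.

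Ribosome-bound RNA differed broadly between the libraries labelled knockout and control. Of 13375 genes tested, 3257 differed between knockout and control at an adjusted p under 0.05, 1461 higher and 1796 lower in the knockouts (edgeR quasi-likelihood test with batch as a term). The median log2 fold change was 0.71 among the higher and -0.86 among the lower genes, with a median SE of 0.19, and 1144 genes changed at least 2-fold. In 1734 genes (13.0%) the values of the 4 knockouts and 7 controls did not overlap, where free splits of 11 libraries give 0.606% by chance, a share that ignores the uneven batches. The median within-batch log2 ratio of the higher genes was 0.82 in batch 1, 0.20 in batch 2 and 0.87 in batch 3, and that of the lower genes was -1.0, -0.25 and -1.06. The first principal component held 36.5% of the variance and placed knockouts F371 (-61.4), M374 (-90.7) and M456 (-52.7) apart from the controls (11.9 to 42.7), with knockout M390 of batch 2 between them at -6.72. The count fell to 335 without knockout M456 and to 522 without control M379, and to 0 by edgeR with the purity score or with the library total as a covariate, where 1026 and 1841 genes had an unadjusted p under 0.05.

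**Figure D1:**
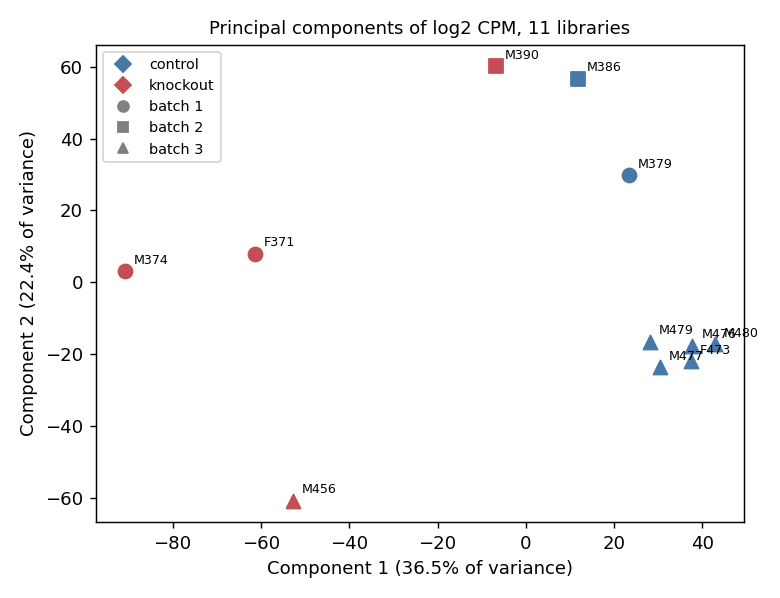
Each point is a library, placed by its first and second principal component of log2 CPM; colour gives the genotype and shape the batch. Knockouts F371, M374 and M456 sit at -61.4, -90.7 and -52.7 on the first component, knockout M390 at -6.72, and the controls between 11.9 and 42.7.

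Among named genes, the steepest rise was that of Eif3j2 (ENSMUSG00000043424, chromosome 18), a copy of a translation initiation factor subunit, from 0.832 CPM ± 0.418 in controls to 17.5 CPM ± 6.08 in knockouts (SD, n = 7 and 4). Its log2 fold change was 4.01 ± 0.46 (SE, edgeR adjusted p = 0.00123), and its within-batch log2 ratios of 3.54, 3.14 and 3.57 were of similar size in all 3 batches. The histone gene Hist2h3c2 rose by 3.77 ± 0.54 and the serine protease gene Prss23 by 3.55 ± 0.86 on the log2 scale. The transcription factor genes Otx2, also a choroid plexus marker, Bhlhe22 and Sox1 rose by 3.17 ± 0.66, 2.93 ± 0.32 and 2.81 ± 0.45. The double-stranded RNA sensor gene Tlr3 rose by 3.26 ± 0.82, Cd274, which encodes PD-L1, by 3.03 ± 0.77 and the interleukin 17 receptor gene Il17ra by 2.71 ± 0.60. Mdfic, the arginine transporter gene Slc7a2 and Fibin completed the 12, at 3.35, 2.75 and 2.64. Eif3j2 and Hist2h3c2 have near-identical copies elsewhere in the genome, so the reads assigned to them are uncertain.

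The steepest falls took several genes to the detection limit. The actin bundling protein gene Vil1 and Cabcoco1 had 107 and 113 reads in the controls and 0 in the 4 knockouts, which makes them at least 15.2-fold and 16.1-fold lower against the floor of 3 counts over the group. Men1, which encodes menin, the tumour suppressor of multiple endocrine neoplasia, had 180 reads in the controls and 2 in the knockouts, a control to knockout ratio of 38.4 (95% counting interval 10.5 to 319). The alpha-protocadherins Pcdha9 and Pcdha7, cell surface molecules of neuronal self-recognition, had ratios of 39.7 (10.8 to 330) and 33.1 (9.0 to 275). Ccdc194, the innate immune kinase gene Alpk1, Lrrc2 and the vitamin K dependent carboxylase gene Ggcx had 1 to 3 reads in the knockouts, with ratios of 37.5 (6.56 to 1499), 26.0 (7.05 to 217), 18.6 (4.98 to 156) and 18.9 (6.33 to 92.9). These bounds and ratios pool reads over batches, and batch 3 holds 5 controls and 1 knockout. Batch-adjusted log2 fold changes were -4.42 ± 0.85 for Men1, -3.87 ± 0.81 for Pcdha9 and -3.84 ± 0.85 for Pcdha7 (SE). For Men1, Pcdha9 and Pcdha7 these were smaller falls than the pooled ratios give. For Ccdc194, Alpk1, Lrrc2 and Ggcx the adjusted values were -4.83 ± 1.03, -4.63 ± 0.89, -4.51 ± 0.96 and -3.66 ± 0.94. Aff2, the gene silenced in fragile XE syndrome, fell by 3.81 ± 0.70 on the log2 scale, from 11.9 CPM ± 7.96 to 0.394 CPM ± 0.277 (SD). The small heat shock protein gene Hspb6 fell by 3.76 ± 0.81, with within-batch log2 ratios of -5.98, -0.58 and -5.03, and the antisense transcript Rbm3os by 3.87 ± 0.96. Protocadherin alpha genes share their last exons, and Rbm3os overlaps Rbm3, so the split of reads in these cases is uncertain.

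**Figure D2:**
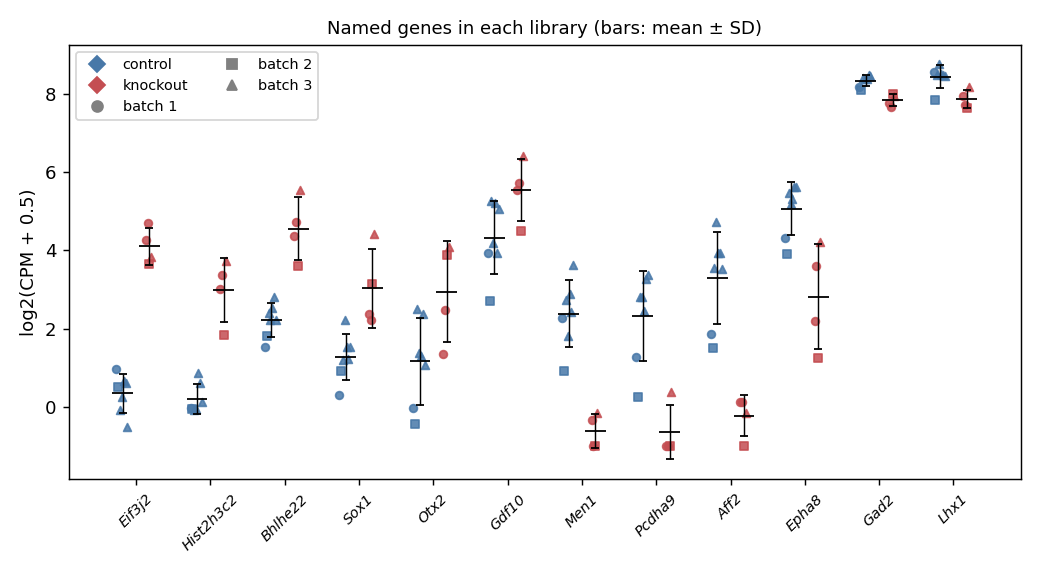
The 12 genes shown were picked from the named genes after their values were seen. Each point is a library's log2(CPM + 0.5) for the gene on the horizontal axis; colour gives the genotype, shape the batch, and black bars the mean ± SD of 7 controls and 4 knockouts. Eif3j2 averaged 17.5 CPM in knockouts and 0.832 CPM in controls, and Aff2 0.394 CPM and 11.9 CPM.

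Purkinje cell identity genes moved in both directions by small amounts. Of 27 markers tested, 4 rose and 5 fell (5 and 7 when adjusted over the list alone), with a median log2 fold change of -0.07 and no shift against other genes (camera adjusted p = 0.90). Foxp2, a transcription factor of Purkinje cells, rose by 0.51 ± 0.12, the calcium buffer gene Pvalb by 0.46 ± 0.12 and Car8 by 0.36 ± 0.10. Lhx1, a transcription factor of Purkinje cell specification, fell by 0.45 ± 0.11 (log2, SE). In the controls alone Pvalb and Car8 were lower in the deepest library than in the shallowest. They were at 194 and 650 CPM in M480 (5.14 M reads) and at 230 and 712 CPM in M476 (4.09 M). Whether depth adds to their rise in knockouts was not tested. Among genes of zebrin-negative Purkinje cells, 3 of 8 rose. These were the neurofilament genes Nefl (0.30 ± 0.08), Nefh (0.41 ± 0.13) and Nefm (0.33 ± 0.11). The camera adjusted p was 0.27 for that list. All 3 were also lower in control M480, at 273, 207 and 275 CPM, than in M476, at 281, 328 and 383 CPM. Nefm was lower still in control M386 of batch 2, at 176 CPM, so its order in the controls is not by depth alone. Whether depth adds to the rise of these 3 genes was not tested. Of the 6 genes of zebrin-positive cells only Tshz1 rose, by 1.2 ± 0.20 (list adjusted p = 0.56).

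Markers of granule cells, small excitatory neurons of the cerebellar cortex, rose together in the knockouts. Of 16 tested, 11 rose and 0 fell (13 rose over the list alone), among them the transcription factor genes Etv1 (1.71 ± 0.29) and Zic1 (1.37 ± 0.22), and Cbln1 (1.04 ± 0.21), which encodes a synapse organiser (camera adjusted p = 0.000286; adjusted p = 0.61 with an estimated correlation). Bergmann glia and astrocyte markers behaved alike, with 8 of 17 higher and 0 lower (13 over the list alone), including the growth factor gene Gdf10 (1.71 ± 0.29), the water channel gene Aqp4 (1.42 ± 0.28) and the glutamate transporter gene Slc1a3 (0.84 ± 0.18; list adjusted p = 0.000286; adjusted p = 0.61 with an estimated correlation). Of 18 oligodendrocyte markers, 4 rose (7 over the list alone), with Ndrg1 at 2.62 ± 0.55 and Gjc3 at 1.51 ± 0.31 (adjusted p = 0.00352; adjusted p = 0.61 with an estimated correlation). These 3 calls were lost without the batch term (adjusted p = 0.052, 0.052 and 0.54), with the purity score as a covariate (0.69, 0.65 and 0.71; the score is built from these markers, so this loss follows from its definition) and with the library total (0.071, 0.076 and 0.076), and by fry, which tests a list against no change, the oligodendrocyte list did not pass (0.053).

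The other cell type lists did not pass as groups by camera with the chosen filter and all libraries. Of 11 microglia markers 3 rose, with Laptm5 at 1.63 ± 0.41, C1qa at 1.30 ± 0.45 and Csf1r at 1.47 ± 0.51 (list adjusted p = 0.11, but 0.0074 without control M379, 0.040 without a filter and 0.033 in animals tagged M). Of 13 interneuron and unipolar brush cell markers 6 rose and 1 fell, with the receptor tyrosine kinase gene Kit at 1.91 ± 0.38 and Tfap2b at 1.89 ± 0.49 (adjusted p = 0.078). That list passed without M374, M379, M390, F473, M477 or M479 (0.023 to 0.035), without batch 2 (0.037), without a filter (0.0054), with 1 CPM in 4 libraries (0.037), thinned (0.023) and by fry (0.046). Choroid plexus markers had 2 of 6 higher, Otx2 and Enpp2 (0.97 ± 0.19; adjusted p = 0.19, and 0.0074 without control M379), and endothelial and mural markers 1 of 16 (adjusted p = 0.25). Pdgfra, a gene of oligodendrocyte precursors, rose by 1.92 ± 0.64, and with 2 members measured its list was not tested. A purity score, the mean log2 CPM of the Purkinje markers minus that of the granule cell, glial and oligodendrocyte markers, was lower in the knockouts of each batch. It was 3.46 and 2.80 against 4.11 in batch 1, 3.78 against 4.12 in batch 2, and 2.52 against 3.15 to 3.68 in batch 3, a within-batch difference of -0.79 (two-sided exact permutation p = 0.0278, the smallest possible).

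**Figure D3:**
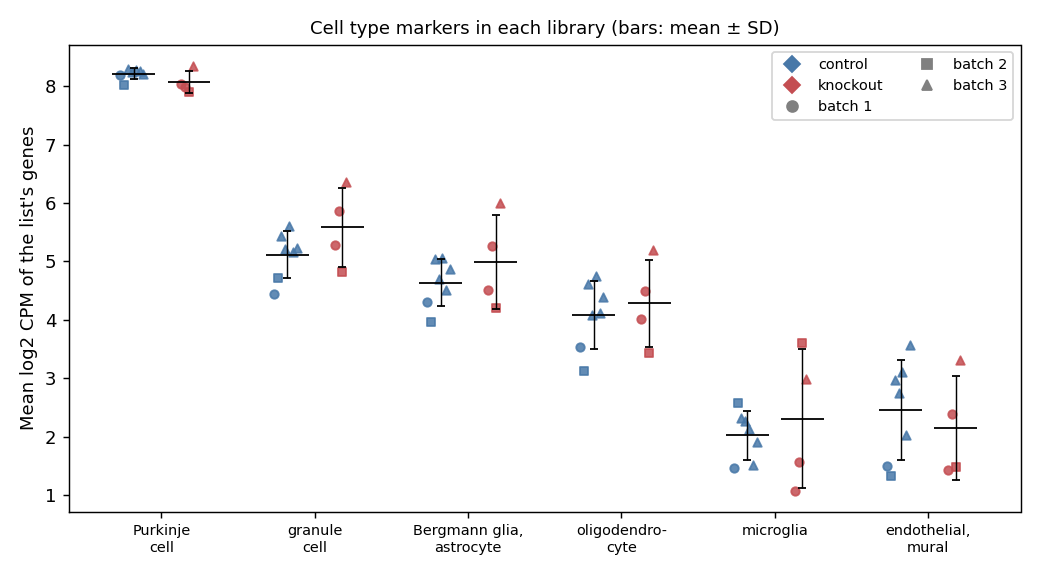
Each point is a library's mean log2 CPM over the genes of a marker list; colour gives the genotype, shape the batch, and black bars the mean ± SD of 7 controls and 4 knockouts. Within each batch the granule cell means of the knockouts lie above those of the controls, while the Purkinje cell means lie within 7.91 and 8.35 in all 11 libraries.

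In the angiopoietin-Tie pathway, which Tie2 starts, 3 of 21 genes rose and 1 fell. The regulatory and catalytic subunit genes of phosphoinositide 3-kinase, Pik3r1 and Pik3ca, rose by 1.12 ± 0.21 and 0.50 ± 0.11, and Angpt1, which encodes the main activating ligand of Tie2, by 1.30 ± 0.41 (5.68 CPM ± 2.23 to 15.1 CPM ± 2.75, SD). Akt1, a kinase activated downstream, fell by 0.67 ± 0.13, from 150 CPM ± 19.3 to 86.1 CPM ± 9.98. All 4 kept their sign within the 3 batches, and the list as a group did not pass (camera adjusted p = 0.29). Genes induced by FoxO transcription factors, which Akt holds back, shifted upward, with 6 of 17 higher and 1 lower (9 and 1 over the list alone). Gadd45a rose by 1.48 ± 0.26, the transcriptional repressor gene Bcl6 by 1.15 ± 0.25 and Trib1 by 0.45 ± 0.11, while the catalase gene Cat fell by 0.97 ± 0.22 (camera adjusted p = 0.00777; adjusted p = 0.61 with an estimated correlation, 0.052 without the batch term, 0.37 with the purity score and 0.071 with the library total). None of the 7 VEGF ligand and receptor genes passed (edgeR adjusted p; list adjusted p = 0.90).

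Genes of axon and dendrite guidance had 7 of 43 members higher and 1 lower (6 and 1 over the list alone; list adjusted p = 0.18, and 0.018 without a filter). The ephrin receptor gene Ephb1 rose by 1.69 ± 0.37 and the semaphorin genes Sema6b and Sema4f by 1.06 ± 0.28 and 0.75 ± 0.18, while Epha8 fell by 1.59 ± 0.34, from 35.9 CPM ± 13.8 to 8.90 CPM ± 7.39 (SD). Epha8 was lower in each batch, by log2 ratios of -1.27, -2.66 and -1.24, whereas Sema6b had a ratio of -0.56 in batch 2. Regulators of dendrite growth had 6 of 46 members higher and 6 lower (adjusted p = 0.81). Cdk5r1, the activator of the neuronal kinase Cdk5, rose by 0.68 ± 0.17, and the Reelin adaptor gene Dab1 fell by 0.41 ± 0.09.

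Synaptic genes were divided in direction. At excitatory synapses 5 of 38 genes rose and 7 fell (6 and 9 over the list alone; list adjusted p = 0.90). Homer2 (1.69 ± 0.33) and the AMPA receptor subunit gene Gria4 (1.24 ± 0.27) were higher, and the scaffold gene Shank2 fell by 0.53 ± 0.12. Its within-batch log2 ratios were -0.51, -0.41 and -0.61. The means, not adjusted for batch, were 577 CPM ± 155 in controls and 327 CPM ± 80.4 in knockouts (SD). Of 20 genes of inhibitory transmission 2 rose and 3 fell (adjusted p = 0.87), with Gad2, an enzyme of GABA synthesis, down by 0.38 ± 0.09, Gabbr2 down by 0.36 ± 0.09 and Iqsec3 down by 1.10 ± 0.26. Among vesicle release genes Napa, Syn1 and Vamp1 fell by 0.61 ± 0.11, 0.58 ± 0.15 and 0.45 ± 0.14, and Syt1 rose by 0.59 ± 0.17 (1 higher and 3 lower of 30; adjusted p = 0.90). Of 41 channel and calcium handling genes 6 fell and 1 rose (1 fell over the list alone; adjusted p = 0.90), and the channel partner gene Kcnip1 was the one named, with a fall of 0.75 ± 0.15. Of 19 matrix and perineuronal net genes 1 rose, Cspg5, by 1.67 ± 0.38 (adjusted p = 0.54).

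Nuclear genes of oxidative phosphorylation shifted upward, with 17 of 69 higher and 4 lower (24 and 7 over the list alone; camera adjusted p = 0.000811; adjusted p = 0.73 with an estimated correlation). Ndufb5 of complex I and Cox4i1 of cytochrome oxidase rose by 0.51 ± 0.12 and 0.49 ± 0.13, while Cyc1 and Ndufv1 fell by 0.59 ± 0.13 and 0.41 ± 0.10. The mean level of the 17 higher genes fell with the library total in the 7 controls alone, with a slope of -1.13 ± 0.0991 log2 CPM per doubling (Pearson r = -0.981, exact permutation p = 0.000595; Spearman rho = -0.964, exact permutation p = 0.00278). Without the 2 controls farthest from the median total r was -0.976, and in the 5 controls of batch 3 the slope was -1.02 ± 0.0704. The list call was lost without knockout M456 (adjusted p = 0.23), by fry (0.17) and with the library total as a covariate (0.26, direction turned). None of the 7 mitochondrially encoded genes passed over all genes (3 over the list alone; list adjusted p = 0.11, but 0.010 without knockout F371, 0.0074 without control M379, 0.021 without a filter and 0.011 in animals tagged M), and mt-Nd1, mt-Nd5 and mt-Nd6 had log2 fold changes of 0.44 ± 0.16, 0.75 ± 0.28 and 0.62 ± 0.23. Of 78 ribosomal protein genes 4 rose and 2 fell (adjusted p = 0.41, and 0.011 with the purity score as a covariate), with Rpl27a at 1.10 ± 0.16 and Rpl10a at -1.78 ± 0.42; such genes have many processed copies.

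**Figure D4:**
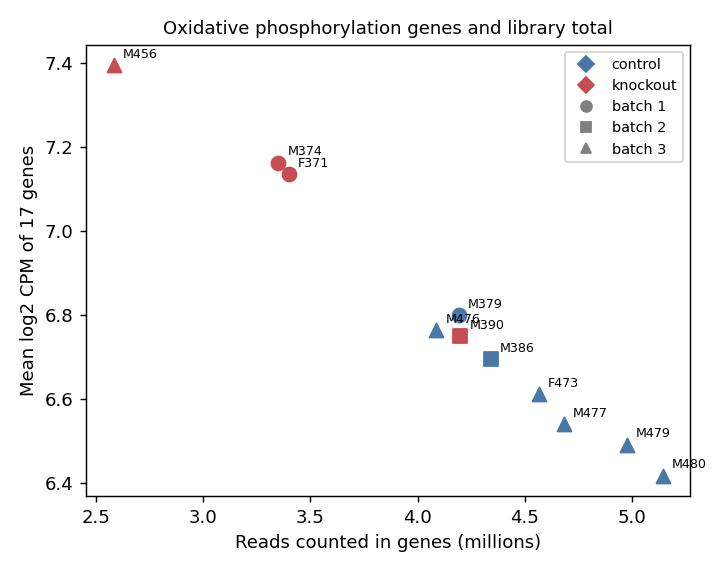
Each point is a library; the horizontal axis gives reads counted in genes in units of M, the vertical axis the mean log2 CPM of the 17 oxidative phosphorylation genes that rose in knockouts. Knockouts and controls lie along a common line, from 7.39 in knockout M456 at 2.58 M reads to 6.42 in control M480 at 5.14 M reads.

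Immediate early genes, which neurons induce on activity, were higher as a group, with 3 of 12 higher and 0 lower (camera adjusted p = 0.00352; adjusted p = 0.23 with an estimated correlation). Egr1 rose by 1.58 ± 0.28, from 13.7 CPM ± 5.05 to 36.1 CPM ± 17.3 (SD), Jun by 1.18 ± 0.25 and Nr4a3 by 1.11 ± 0.37. The call was lost without control M386 (adjusted p = 0.060) and without batch 2 (0.050). In the list of unfolded protein and heat shock genes 2 of 21 rose and 7 fell (3 and 8 over the list alone; camera adjusted p = 0.25, and 0.015, lower, by fry). The stress transcription factor genes Atf4 and Atf5 rose by 0.51 ± 0.11 and 1.13 ± 0.25, while Xbp1 fell by 0.75 ± 0.17 and Chac1, an enzyme of glutathione breakdown, by 1.97 ± 0.49. Cholesterol synthesis genes were split, with Cyp51 (0.91 ± 0.19) and Hmgcs1 (0.60 ± 0.18) higher, and Nsdhl down by 2.18 ± 0.39 and Acat2 by 0.69 ± 0.20 (2 and 2 of 19; adjusted p = 0.90).

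Genes near Tek, which a floxed allele can bring along from another strain, were not called more often than others beyond the error of the comparison. Of 118 tested genes within 20 Mb on chromosome 4, 35 differed (29.7%). This compares with 24.8% of the others, an odds ratio of 1.28 (95% interval 0.836 to 1.93, two-sided Fisher's exact test p = 0.24). Within 10 Mb the odds ratio was 1.18 (0.619 to 2.16, Fisher's exact test p = 0.54). Over all of chromosome 4, 27.6% differed against 24.6%, an odds ratio of 1.17 (0.990 to 1.37, Fisher's exact test p = 0.058).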

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

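The tests of dilution, of marker lists moving apart, of thinning, of the library total as a covariate, the splits that exchange 1 knockout for 1 control and the second test of a wrong label were chosen only after the result they bear on was seen; the oxidative phosphorylation slope was set before its value was computed but after the ratios had been seen to follow depth.

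The first pattern is the breadth of the change, 3257 genes. Of 100 drawn splits of the libraries into 4 and 7, 1 gave as many genes, the real one. The same held for the 1461 higher and 1796 lower genes, and the highest of the others was 0. The draw ignored the batches, within which only 36 arrangements exist, so it does not exclude chance for this design. Of 28 splits that exchange 1 knockout for 1 control, mostly not drawn, 7 gave any gene. The highest gave 2241 (knockout F371 for control M386). There both batch 2 libraries fell in the group of 4, so with batch in the fit the calls rested on knockouts M374 and M456. Exchanging M374, M390 or M456 for M386 gave 24, 423 and 0 genes. Unequal counting error alone is argued against, since 2985 of the calls remained after thinning. Thinning keeps each gene's expected share of reads, so it cannot test counts that level off with depth. With the library total as a covariate edgeR called 0 genes (1841 at an unadjusted p under 0.05, medians 0.46 ± 0.27 and -0.58 ± 0.28, SE). That alone decides nothing on library yield, as total and genotype go together. A later test, set before its result, used the slope on the total in the 7 controls. For the higher genes it predicted -0.11 ± 0.14 (SE), against a median of 0.71 and within the bound set to exclude yield. The 5 controls of batch 3 gave -0.022 ± 0.19, past that bound with 2 SE added. For the lower genes it predicted -0.076 ± 0.13, far smaller than -0.86 but past the bound with 2 SE added. Most knockout totals lay below every control, so for both sets a part from yield stays open. The slope is also that of a set mean, in which members with opposite slopes cancel. The 17 higher oxidative phosphorylation genes belong to the higher set and had a slope of -1.13 ± 0.0991 in these controls. The test thus says nothing on single members. Dilution by RNA of other cells would lower no transcript by more than one found only in Purkinje cells. The median of the lower genes was -0.86, while the 27 Purkinje cell markers as a set barely fell (mean -0.05, SD 0.29). The lower genes were chosen for falling in this same fit, which favours such a gap, so it does not settle what part dilution has. For the higher genes RNA of other cells and an effect of genotype cannot be told apart: the fitted changes of 7 other cell type lists, of which 3 passed as groups, ran from 0.35 ± 0.36 (endothelial, SE) to 0.83 ± 0.22 (granule), a spread of 0.482 that within-batch rearrangements often reach (exact permutation p = 0.72), and purity differs by genotype in every batch.

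The second pattern is that 6 gene lists passed. As many passed in 45 of 100 drawn splits, the highest other giving 12, so chance cannot be excluded for the number of lists. For the rise of the 17 oxidative phosphorylation genes, a candidate explanation is that counts of short, abundant transcripts level off with depth, for example after removal of duplicate reads, which was not checked. The slope in the 7 controls was -1.13 per doubling, where -0.5 or below had been set as its sign, and with the depth gap it predicts a rise of 0.54 against the 0.49 observed. With the library total as a covariate the list did not pass and its direction turned (adjusted p = 0.26), but total and genotype go together within batches, so an effect of genotype beyond depth stays open.

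The third pattern is the small change in knockout M390 of batch 2. The effect of genotype differed in batch 2 for 10 genes in an interaction test (edgeR adjusted p, with 2149 at an unadjusted p under 0.05). The interaction ran against the main effect for 91.6% of the called genes. Those genes were called on a main effect set mostly by the other batches, which favours this sign, and no expected share was computed. A wrong label and a smaller effect in this animal cannot be told apart. With the labels of M390 and M386 exchanged the fit called 423 genes, against 3257 as given, which bears only on an exchange of these labels. Along 4593 genes called without batch 2, M390 differed from control M386 by a median log2 of 0.13. That lies between the median (0.083) and the highest (0.17) of the 10 pairs of batch 3 controls. Knockout and control pairs of the other batches reached 0.80 to 1.02, but the genes were called from those same libraries, which raises these values. As this left it open, a second test was added, and it left it open too: M390 lay beyond all controls by 1 log2 unit in the knockout direction at 98 genes and in the opposite direction at 23, against 67 and 61 for M386. Eif3j2 was at 12.0 CPM in M390 and at most 1.45 CPM in any control. Hspb6 went the other way, at 20.6 CPM in M390, at most 0.803 CPM in the other knockouts and 27.2 to 54.2 CPM in controls. Each was picked from the named genes, so neither decides it.

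Of 258 groups of values examined, 17 (6.59%) held 1 library far from the rest, where chance gives about 1 in 20 in a uniform group. The controls span the batches, with M386 the only one of batch 2 and M379 of batch 1, so library and batch cannot be told apart there. Values are the gap to the nearest library over the group's range. Control M386 was lowest among controls for Lhx1 (0.673), Hepacam (0.710), Gjc3 (0.652), Ttr (0.578), Akt1 (0.574) and the Purkinje cell marker mean (0.620). Control M476 was lowest for Vil1 (0.632), Kit (0.578) and Hmgcs1 (0.662), and control M379 for C1qa (0.604). Among knockouts M390 was lowest for Homer2 (0.891) and Nefm (0.843). In 5 genes near 0 reads a single knockout had any, a ratio of 1 each: M456 for Ccdc194, Pcdha9 and Pcdha7, M390 for Alpk1 and F371 for Rbm3os.

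Among reads that the comparisons did not use, alignments to several places were 0.915 percentage points more frequent in knockouts within batches (exact permutation p = 0.0278, the smallest of 36 arrangements), and reads outside genes 1.35 points more frequent (exact permutation p = 0.28).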

How the results depend on the processing

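The library total, thinning and leaving out batch 2 were chosen after seeing the data. The purity and library total covariates took all calls away: both gave 0 genes changed, 0 higher and 0 lower by edgeR (1026 and 1841 genes at an unadjusted p under 0.05), where the median log2 change of the higher genes went from 0.71 (median SE 0.18) to 0.44 (0.33) and 0.46 (0.27) and that of the lower from -0.86 (0.21) to -0.55 (0.36) and -0.58 (0.28); both covariates follow genotype within batches, the errors widened and the medians shrank, and which of these ended the calls was not tested. Leaving out 1 library gave 335 (without knockout M456) to 4649 genes changed (without knockout M390), 64 to 2269 higher and 216 to 2397 lower; without control M379, the partner of both batch 1 knockouts, 522 were left. An adjusted p of 0.01 left 1271 genes, and without batch 2 2262 were higher. All other settings kept the counts of genes within 1.5 times, DESeq2 giving 4174. Gene list calls numbered 2 without the batch term, 11 without a filter, 3 with the purity score, 1 with the library total, 0 with an estimated correlation and 5 to 10 with a library left out. Tek turned to -0.64 without the batch term, -2.76 with purity and -0.40 with batch as a random block, and stayed at 0.32 to 1.83 without single libraries; at 0 to 40 reads depth limits it. Of the 98 named genes that passed, 1 turned with purity; of those that had not passed, mt-Nd5 (-0.48) turned with purity and mt-Nd1 (-0.11) with the library total. Directions of lists that turned (adjusted p) were, without the batch term, endothelial (0.946), dendrite (0.685), inhibitory (0.542) and matrix genes (0.976); without a filter VEGF (0.960); with 1 CPM in 4 libraries Purkinje, excitatory and channel genes (0.989 each); in animals tagged M Purkinje, excitatory, channel, cholesterol and vesicle genes (0.973 each). With purity they were oligodendrocyte (0.709), endothelial (0.323), angiopoietin-Tie (0.809), dendrite (0.646), inhibitory (0.889), mitochondrially encoded (0.702) and matrix genes (0.992); with the library total VEGF (0.750), excitatory (0.751), oxidative phosphorylation (0.258), mitochondrially encoded (0.324) and ribosomal genes (0.433). Without batch 2 they were Purkinje and channel (0.842 each), cholesterol and vesicle genes (0.952 each); with voom dendrite (0.976), thinned cholesterol (0.995), by fry inhibitory genes (0.978). Without single libraries the adjusted p of lists that turned in at least 1 case ran from 0.227 to 0.997 for Purkinje, 0.498 to 0.979 for dendrite, 0.865 to 0.998 for excitatory, 0.664 to 0.997 for channel, 0.718 to 0.997 for cholesterol and 0.413 to 0.997 for vesicle genes. List tests were not run with the DESeq2 Wald test or the random block. The cause of these turns was not tested.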

Other observations

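The families and the criterion of change in every batch described here were chosen after the table of all genes was seen; 28 families were screened by gene symbol and adjusted together, of which 4 passed (camera) and 0 with an estimated correlation, and the members named were picked by eye. The alpha-protocadherin cluster, whose members give neurons distinct surface identities and take part in dendrite self-avoidance, fell as a family. Of 11 members tested, 7 fell and 0 rose (edgeR adjusted p), also with the other scalings, and the family median log2 fold change was -3.28, with within-batch medians of -2.51, -0.85 and -2.61 (camera adjusted p = 1.44e-05; adjusted p = 0.40 with an estimated correlation). The most highly counted member, Pcdhac2, fell from 93.1 to 11.2 mean CPM (log2 fold change -2.71 ± 0.44 SE) and Pcdha2 from 443 reads in the controls to 8 in the knockouts. In the neighbouring families 1 of 15 gamma-protocadherins was lower, with within-batch medians of -0.63, -0.55 and -0.58, and 1 of 20 beta-protocadherins was higher and 1 lower; differences between families were not tested. Alpha- and beta-tubulins had 5 of 11 members lower and 0 higher (camera adjusted p = 0.17), among them Tuba8 (-1.01 ± 0.18) and the neuronal Tubb3 (-0.50 ± 0.11). Of 12 transcripts with a Sox symbol 4 rose and 0 fell, the noncoding Sox2ot and the transcription factor genes Sox1, Sox2 (2.23 ± 0.62) and Sox4, with within-batch medians of the family of 1.18, -0.12 and 0.98 (adjusted p = 0.0251; adjusted p = 0.72 with an estimated correlation). Genes with an Lsm or Snrp symbol, mostly of the spliceosome, had 6 of 26 higher and 2 lower (adjusted p = 0.0268; adjusted p = 0.93 with an estimated correlation), and histone genes 4 of 20 higher and 0 lower (adjusted p = 0.0424; adjusted p = 0.40 with an estimated correlation).

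Among called genes of at least 1 mean CPM without a predicted-gene symbol, 176 changed at least 2-fold in the same direction in each of the 3 batches, 91 higher and 85 lower; the examples were picked after their values were seen. The linker histone gene Hist1h1c rose by 2.08 ± 0.24, with log2 ratios of 2.67, 1.49 and 1.93, and the transcription factor gene Tcf4 by 1.47 ± 0.20, from 51.7 CPM ± 12.9 to 132 CPM ± 45.7 (SD, n = 7 and 4). The heat shock transcription factor gene Hsf1 fell by 1.39 ± 0.27 and the endophilin gene Sh3gl1 by 2.35 ± 0.31, while its relative Sh3gl3 rose by 2.31 ± 0.42. Ubxn7 rose by 1.10 ± 0.18 with ratios of 1.10, 1.09 and 1.09.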
